A study of Mus musculus with 4 samples.

How the data were processed

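Expression was measured by RNA sequencing in 4 libraries, 2 from Usp25+/+ and 2 from Usp25-/- mice. Per the labels' protocols, poly(A) RNA was isolated with oligo(dT) beads and sequenced as paired reads without strand information, so that reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes name cutadapt, TopHat2 2.1.1, Cufflinks and the mouse build mm9. The annotation, the filters and the scaling used are not given in the sources used here. The deposited values are taken here as FPKM, fragments per kilobase of transcript scaled by the mapped fragments of the library, because Cufflinks is named in the submitters' processing notes and the library totals differ (526652 to 565645). No header or label states the unit, and FPKM scales each library by its own total, so that a few abundant genes can lower all others. Whole reads could not be recovered from the values, so the depth per library is unknown, and no counting interval or detection limit is given. A value of 0 is reported only as listed at 0.

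Groups came from the genotype labels. Animal numbers differ between the genotypes, so no pairing was used. The labels name separate animals, and n is 2 in each genotype. Gene lists, tests, thresholds and the alternatives were chosen before the data were examined, with the following exceptions. The lung, alveolar macrophage, general epithelial, stomach, visceral smooth muscle and ribosomal RNA genes were chosen afterwards. So were the tests of tissue, of animal 139, of epithelial share and of stomach genes. Values were taken as log2(FPKM + 1), which understates changes of low genes, and genes with a mean of at least 1 FPKM were tested (12011 of 24421). The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 residual degrees of freedom per gene, the spread was moderated across genes. The gap of a gene was the lowest library of a genotype minus the highest library of the other. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 27 lists, with an estimated correlation and fry as alternatives. The lists held 649 symbols, of which 644 were found. Fry tests whether the genes of a list move on balance in one direction, and does not compare them with other genes.

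Genes were named by a fixed rule. It took Usp25 and Usp28, then the 12 genes in each direction with the largest change among those past the threshold, filled up with the widest gaps among genes with a mean of at least 5 FPKM. Predicted genes, pseudogenes and antigen receptor segments were passed over. For each list, the examples given were taken from the 4 tested members with the largest absolute log2 fold change, and not every list or member is shown, a looser choice than the planned 2 to 4 largest of each list. Coordinates came from GENCODE vM1 on NCBIM37, the assembly also called mm9, and 20836 of the 24421 symbols matched it.

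The tests were tried on simulated data with 12011 genes, 20 simulations and 200 changed genes in each. Limma recovered 0.896% of changes of 1 log2 unit, 46.1% of 2 and 97.1% of 4, and 202 of 2114 calls were false, more than the threshold of 0.05 intends. The noise of each gene was drawn from its moderated variance, and moderated variances differ less between genes than unmoderated ones. These recovered shares may therefore be too high for the data. There, Gkn1 with a log2 fold change of 4.36 had a limma adjusted p of 0.960. A list shifted by 1 log2 unit was recovered in 20 of 20 simulations with the preset correlation and in 0 of 20 with the estimated one. With the preset correlation, 7 of 520 tests of unchanged lists passed. Each gene was simulated independently, while the neutrophil markers of the data had an estimated correlation of 0.98. The simulations therefore cannot show how often the preset test passes unchanged lists whose genes move together. Alternatives were other pseudocounts, filters, scalings, variance models and gaps, and leaving out each library in turn. A genotype left with 1 library was assumed to vary like the other.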

Results

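Poly(A) RNA was sequenced from 4 mice on a C57BL/6 background, 2 with intact Usp25 (Usp25+/+, animals 139 and 140) and 2 lacking it (Usp25-/-, animals 826 and 850). Usp25 encodes a deubiquitinating enzyme, which removes ubiquitin from other proteins. The labels describe the distal colon of females aged 8 weeks that drank 2.5% dextran sulfate sodium (DSS), a polymer that injures the colon epithelium, for 5 days and then plain water for 2 days. The comparison asks how the transcriptome differs between the genotypes after the labelled treatment, and untreated animals were not analysed here. Each library lists 24421 genes in FPKM, and the depth behind these values is unknown. The number of genes above 0 was 20556 in Usp25+/+ 139, 15603 in Usp25+/+ 140, 17242 in Usp25-/- 826 and 15805 in Usp25-/- 850.

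The transcripts of all 4 libraries were at odds with the labelled tissue and sex. The 46 listed genes of absorptive colonocytes and goblet cells had library medians between 0 and 0.297 FPKM. Muc2, the main secreted mucin of the colon, was listed at 0.193, 0.055, 0.0436 and 0 FPKM in animals 139, 140, 826 and 850, and the chloride exchanger Slc26a3 at 0.124, 0, 0.111 and 0 FPKM. Genes known from lung epithelium were abundant, and 16 of them had library medians of 54.0 to 85.5 FPKM. The surfactant protein gene Sftpc stood at 339, 2347, 1376 and 2596 FPKM, Sftpb at 865, 1139, 3284 and 1581 FPKM, and the club cell gene Scgb1a1 at 741, 462, 219 and 567 FPKM. Nkx2-1, a transcription factor of lung and thyroid, stood at 6.70, 13.7, 13.4 and 13.4 FPKM. The Y-linked genes Ddx3y and Eif2s3y ranged from 12.7 to 30.3 and from 27.8 to 44.7 FPKM, while Xist, which is transcribed from the inactive X chromosome of females, did not exceed 0.11 FPKM. The lung genes were chosen after their values were seen. The treatment and age come from the same labels, and no value here checks them. Every value below is therefore given for the libraries as labelled by genotype, without taking them as measurements of the colon or of DSS treatment.

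**Figure D1:**
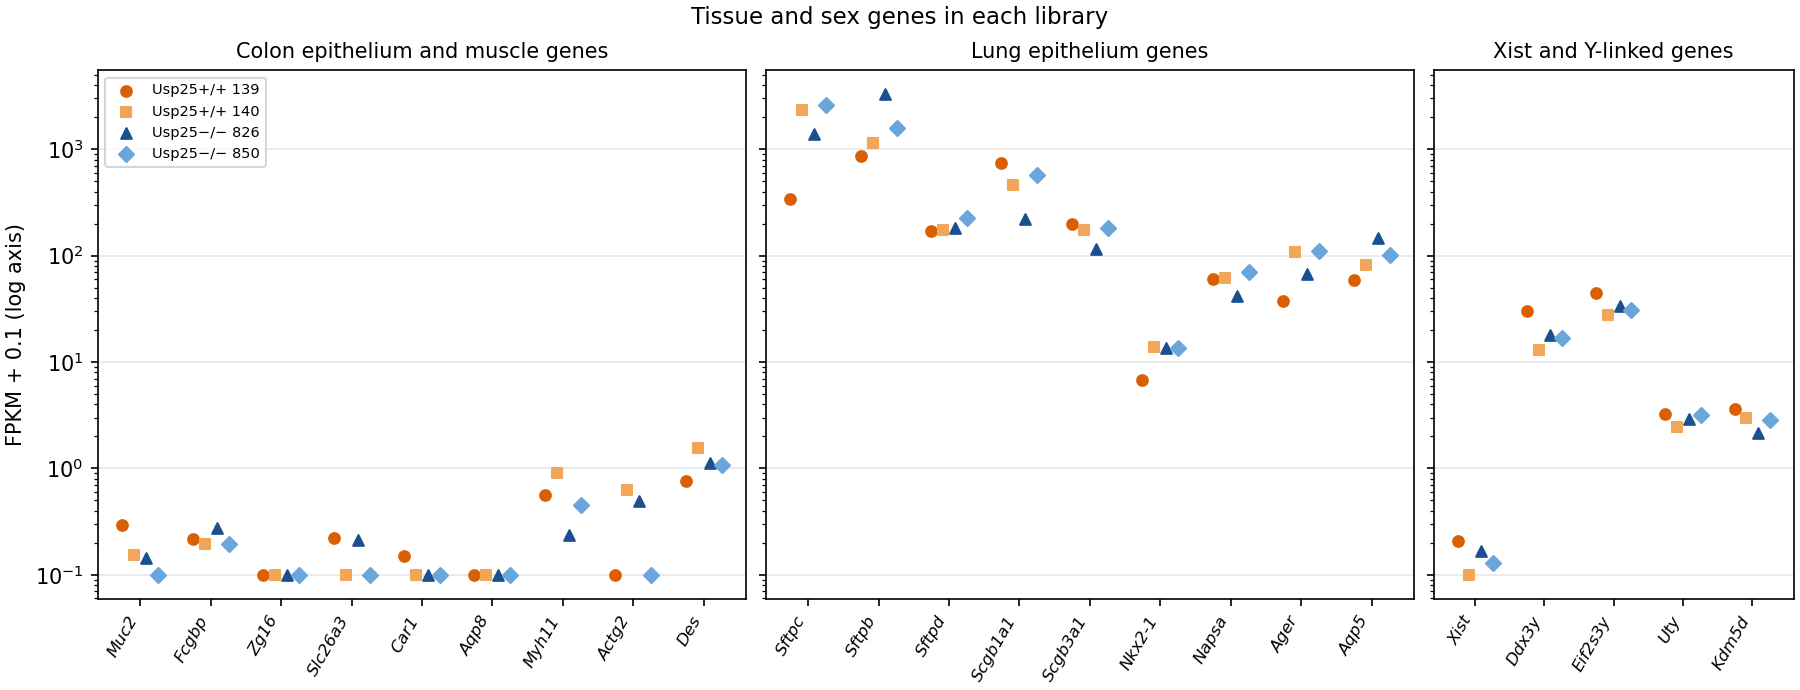
FPKM plus 0.1 on a log axis for genes of colon epithelium and muscle, of lung epithelium, and for Xist and 4 Y-linked genes, with 1 point per library. Sftpc lies between 339 and 2596 FPKM in the 4 libraries, and Muc2 does not exceed 0.193 FPKM.

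The targeted gene followed the genotype labels. Usp25 was listed at 38.5 and 16.6 FPKM in Usp25+/+ 139 and 140, and at 2.65 and 1.71 FPKM in Usp25-/- 826 and 850. The means were 27.5 ± 15.5 against 2.18 ± 0.662 FPKM (SD, n = 2 each). Its log2 fold change on log2(FPKM + 1) was -3.07 (SE 0.47), with an unadjusted limma p of 0.00107 and an adjusted p of 0.960 over 12011 genes. The gene lies on chromosome 16 from 77014314 to 77117024 on the plus strand of mm9, and the part removed in the knockout is not given in the sources used here. Its closest paralog Usp28 had a log2 fold change of -0.43 (SE 0.32). The 18 tested neighbours of Usp25 on chromosome 16 had a median log2 fold change of -0.01 (camera adjusted p = 0.827), with 9 higher and 9 lower.

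No gene passed the threshold between the genotypes. Limma on log2(FPKM + 1) gave 0 of 12011 genes at an adjusted p of 0.05, and 375 at an unadjusted p of 0.05 (254 higher and 121 lower in Usp25-/-), where 600.6 are expected by chance. The smallest adjusted p was 0.374. The 375 became 638 without animal 139 (51.7% higher), 2577 without 140 (50.6% higher), 103 without 826 (62.1% higher) and 374 without 850 (80.5% higher). In 71 genes the libraries of the genotypes lay at least 1 log2 unit apart, 53 of them higher and 18 lower in Usp25-/-. Without animal 140 the balance turned, to 537 higher and 845 lower. The same count was 113 and 26 under the other 2 splits of the 4 libraries into pairs. The genotypes did not overlap in 33.8% of the tested genes, where chance gives 33.3%. With 2 libraries each, an exact permutation test of a single gene cannot give a p below 0.333.

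The genes that stood farthest above in Usp25-/- included secreted products known from the gastric surface epithelium, though none passed the test. The trefoil factor Tff1, on mm9 chromosome 17 from 31298341 to 31301998, was listed at 71.3 and 105 FPKM in Usp25+/+ and at 1848 and 759 FPKM in Usp25-/-, a log2 fold change of 3.76 (SE 0.54; limma adjusted p = 0.960). The gastrokines Gkn1 and Gkn2 had log2 fold changes of 4.36 (SE 0.80) and 3.35 (SE 0.71). Gkn3 and Prap1 were listed at 0 in both Usp25+/+ libraries and above 0 in both Usp25-/- libraries, Gkn3 at up to 22.1 FPKM and Prap1 at 17.7 and 6.63 FPKM in 826 and 850. Dpcr1, a mucin-like gene, stood at 11.5 and 9.28 against 96.1 and 60.3 FPKM. The mast cell proteases Mcpt1 and Mcpt2 had log2 fold changes of 3.20 (SE 0.57) and 2.50 (SE 0.44), with reads that near-identical family members can share. Of the 15 listed mast cell and eosinophil genes, 11 were under 1 FPKM in every library. Il33, an alarmin cytokine of epithelial cells, stood at 30.2 and 35.2 against 268 and 112 FPKM, and the chemokine Ccl7 at 0 and 1.73 against 12.5 and 13.2 FPKM. Anxa10 and Cdc42ep5 had log2 fold changes of 2.65 and 2.39. In each of these widest-gap genes except Ccl7 the value was higher in 826 than in 850.

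The genes that stood farthest below in Usp25-/- held immune receptors and chemokines, again with none past the test. Pira1, an activating receptor of myeloid cells, was listed at 24.4 and 16.5 FPKM in Usp25+/+ and at 0 in both Usp25-/- libraries, and had the smallest limma adjusted p of 0.374. It belongs to a family of near-identical copies, so that its value is uncertain, as are those of H2-Q5, H2-Q6 and Hist2h2aa1. The class I genes H2-Q6 and H2-Q5 had log2 fold changes of -1.95 (SE 0.57) and -1.45 (SE 0.39), and Hist2h2aa1 of -1.27 (SE 0.29). The interferon-induced chemokines Cxcl9 and Cxcl10 were listed at 117 and 465 FPKM in Usp25+/+ 139, at 5.83 and 52.9 in 140, and at 2.18 and 25.4 in 826 and 1.53 and 29.5 in 850. Snai1, a transcription factor of epithelial-mesenchymal transition, had a log2 fold change of -1.63 (SE 0.36). Pip5k1c, Mthfsl, Il1rl2 and Numb had log2 fold changes between -1.09 and -0.93.

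**Figure D2:**
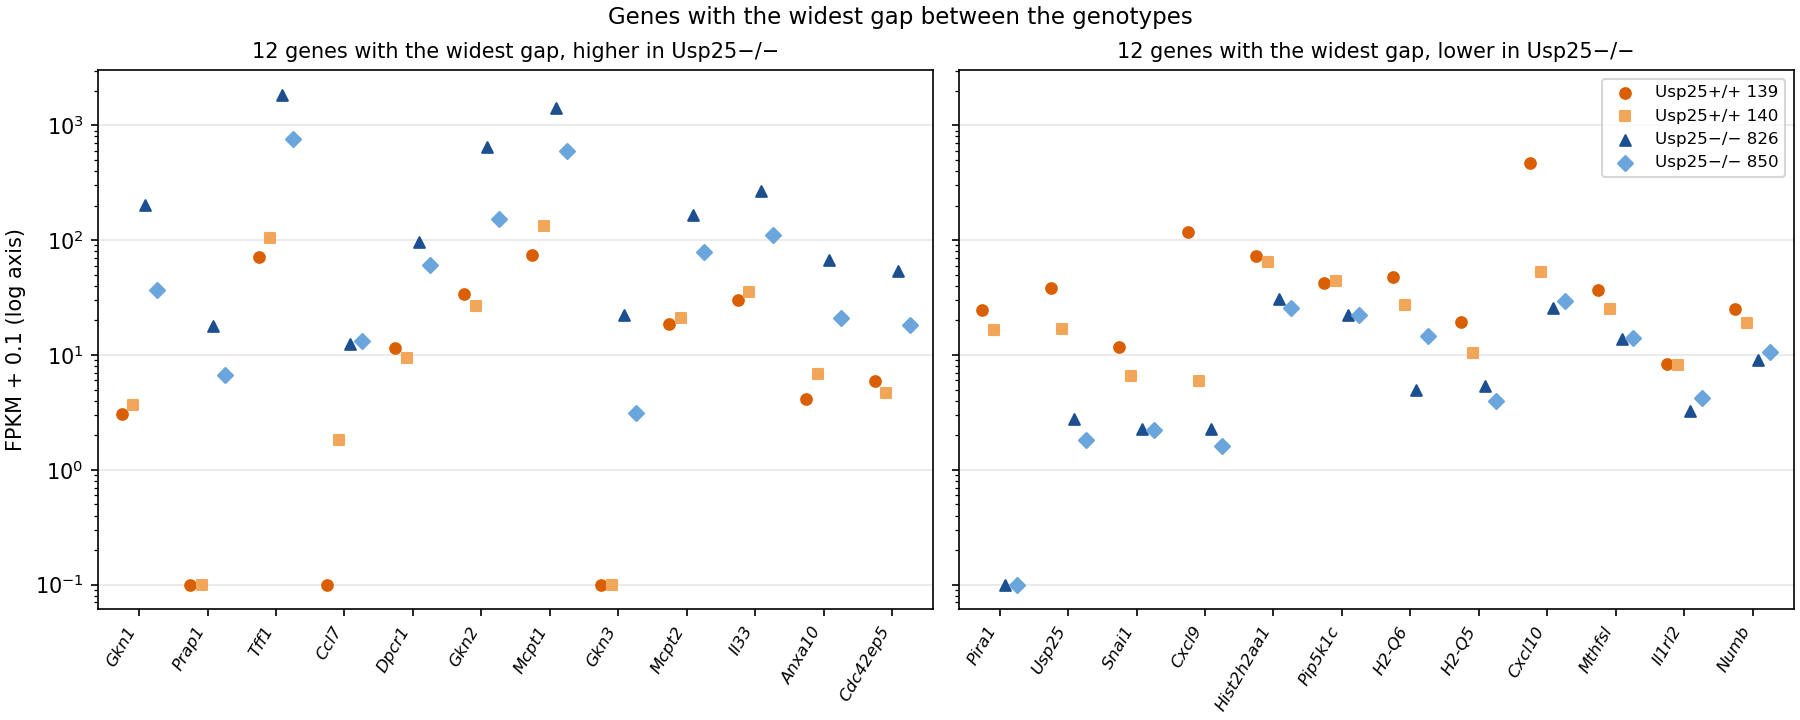
FPKM plus 0.1 on a log axis for the 12 genes with the widest gap in each direction, with 1 point per library and values of 0 drawn at 0.1. Tff1 lies at 71.3 and 105 FPKM in Usp25+/+ and at 1848 and 759 FPKM in Usp25-/-, and Pira1 is listed at 0 in both Usp25-/- libraries.

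Of 27 gene lists fixed beforehand, 12 passed camera with a preset correlation of 0.01, and 0 passed with an estimated correlation or with fry. For each of those 12 the adjusted p = 0.743 with an estimated correlation, a form of the test that recovered 0 of 20 simulated list changes. The other 2 splits of the libraries, which mix the genotypes, gave 16 and 15 lists past the preset test, and 6 of the 12 lists had a smaller adjusted p under at least 1 of them than under the real one. Adjusted over the list alone, limma called 1 chemokine, Ccl7, at a log2 fold change of 3.06 (SE 0.53), against the lower median of its list. It also called Mcpt1 and Mcpt2 in the mast cell and eosinophil list, and 0 members of every other list, against 0 over all genes tested.

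Interferon genes had lower medians in Usp25-/-. All 23 tested type I interferon-stimulated genes had a negative log2 fold change, with a median of -1.30 (camera adjusted p = 4.67e-09; adjusted p = 0.743 with an estimated correlation), and the libraries did not overlap in 10. The preset test gave this list a smaller adjusted p of 1.48e-11 when 139 and 850 were set against 140 and 826, and 4.63e-05 when 139 and 826 were set against 140 and 850. Ifit1, which binds viral RNA, was listed at 56.1 and 1.48 FPKM in Usp25+/+ and at 0.901 and 2.30 FPKM in Usp25-/-, and Rsad2 at 70.1 and 0.829 against 1.31 and 1.91 FPKM. All 23 were highest in animal 139, and without it the median was -0.21 (adjusted p = 0.236), while without animal 140 it was -2.49. The 26 interferon-gamma and antigen presentation genes had a median of -0.92 (camera adjusted p = 5.45e-08, or 0.743 with an estimated correlation). Of these, 21 were lower, 5 higher and 16 lower without overlap. The list also passed preset camera when 139 and 850 were set against 140 and 826 (adjusted p = 0.01). The GTPase genes Gbp2, Irgm1 and Igtp had log2 fold changes of -2.86 (SE 1.41), -2.03 (SE 1.05) and -1.93 (SE 0.93), which shrank to -0.65, -0.48 and -0.55 without animal 139, and in Irgm1 animal 140 lay below 850. Animal 140 lay above both Usp25-/- libraries in 24 of these 26 genes, and without animal 139 the median was -0.67 (adjusted p = 4.89e-09). Without animal 826 it was -0.57 (adjusted p = 1.62e-05).

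Neutrophil and inflammatory genes followed animal 139. The 20 neutrophil markers had a median of -1.55 (camera adjusted p = 1.54e-04; adjusted p = 0.743 with an estimated correlation). All 20 were highest in 139, and 0 separated the genotypes without overlap. The adjusted p of the preset test was smaller under both other splits (3.31e-12 and 4.18e-10). S100a8, a calcium-binding protein of neutrophils, was listed at 19445 and 382 FPKM in Usp25+/+ and at 838 and 536 FPKM in Usp25-/-, and Lcn2, which binds bacterial siderophores, at 5537 and 86.7 against 82.8 and 105 FPKM. Without animal 139 the neutrophil median was 0.81 (adjusted p = 1.63e-08), the opposite direction, and without animal 140 it was -3.91. The 15 antimicrobial and acute-phase genes had a median of -1.15 (adjusted p = 0.00543), the 22 chemokines of -0.81 (0.0399), the 17 inflammatory cytokines of -0.81 (0.0411), the 27 genes of IL-17, TLR and TRAF signalling of -0.55 (1.54e-04) and the 8 Th17 cell genes of -0.49 (0.0436), each with an adjusted p = 0.743 with an estimated correlation. Without animal 139 these medians were, in that order, 0.10 (adjusted p = 0.153), 0.01 (0.460), 0.61 (0.0177, the opposite direction), -0.10 (0.837) and -0.02 (0.924), and without animal 140 they were -2.63, -1.66, -2.15, -0.97 and -1.18. Without animal 850 the adjusted p was 0.671 for cytokines, 0.0648 for chemokines and 0.169 for Th17 cell genes, and without animal 826 the chemokine median was -0.43. Across other filters, pseudocounts and scalings the cytokines passed in 1 of 8, the chemokines in 4 of 8, the antimicrobial genes in 7 of 8 and the Th17 cell genes in 1 of 7. Il33 (2.37, SE 0.49), the cytokine with the largest absolute change, went against the lower median of its list. Saa3 was listed at 4990 and 43.5 against 58.3 and 110 FPKM, Tnf at 305 and 69.2 against 43.7 and 27.1 FPKM, and Nfkbiz, an inducible regulator of NF-kB, at 391 and 81.5 against 73.2 and 61.0 FPKM. Il17a, the cytokine that names the Th17 cells, had a log2 fold change of -0.67 (SE 0.61), or 0.12 without animal 139. Dmbt1, a secreted mucosal glycoprotein, stood apart from its antimicrobial list at 23.9 and 8.12 against 65.6 and 74.2 FPKM.

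Immediate early genes stood lower and proliferation genes higher in Usp25-/-. All 16 immediate early genes had a negative log2 fold change, with a median of -0.49 (camera adjusted p = 1.54e-04, or 0.743 with an estimated correlation). In 10 of them the genotypes did not overlap. The list also passed preset camera when 139 and 850 were set against 140 and 826 (adjusted p = 0.0147). Egr3 and Dusp1 had log2 fold changes of -1.42 (SE 0.80) and -0.85 (SE 0.53), which shrank to -0.21 and -0.23 without animal 139. Of 19 proliferation genes 18 were higher, with a median of 0.34 (camera adjusted p = 2.73e-04; adjusted p = 0.743 with an estimated correlation), and 8 did not overlap. Ube2c, Mcm6 and Rrm2 had log2 fold changes of 0.96 (SE 0.40), 0.93 (SE 0.31) and 0.78 (SE 0.29), and Ube2c fell to 0.55 without animal 826. The immediate early median was -0.74 without animal 140 and -0.30 without 826, and the proliferation median was 0.56 without 140 and 0.15 without 850. These medians and that of the antigen presentation genes (-1.37 to -0.57) kept their direction whichever library was left out, as did those of other lists among the 12. Each such fit leaves 1 library in a genotype. Its list test compares genes with other genes, and cannot show the spread between animals.

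Junction and goblet cell genes had higher medians in Usp25-/-, the junction genes mainly through animal 826. Of 22 epithelial junction genes 18 were higher, with a median of 0.58 (camera adjusted p = 0.00310; adjusted p = 0.743 with an estimated correlation). Without overlap, 7 were higher and 1 was lower, where 33.8% of all tested genes did not overlap. The list also passed preset camera when 139 and 826 were set against 140 and 850 (adjusted p = 0.0149), lower in 140 and 850. Their mean log2(FPKM + 1) was 3.42, 3.05, 3.91 and 3.42 in 139, 140, 826 and 850, so that 850 was level with 139. Cldn7 was listed at 25.6 and 26.7 against 132 and 52.3 FPKM, Cldn2 at 9.25 and 2.83 against 25.7 and 21.8 FPKM, and Cldn1 at 25.8 and 4.15 against 1.36 and 2.44 FPKM. Without animal 826 the median was 0.26 (adjusted p = 0.158), and without animal 140 it was 0.49 (adjusted p = 0.260). The 7 tested goblet cell genes were all higher, with a median of 0.55 (camera adjusted p = 0.0223; adjusted p = 0.743 with an estimated correlation). Their mean was 2.01, 2.35, 2.84 and 2.87 in the same order. Tff3, with the largest change of these 7 at 1.52 (SE 1.01), was listed at 7.25 FPKM in 850 and at 0 in the other 3 libraries. Bcas1 and Sytl2 had log2 fold changes of 1.29 (SE 0.50) and 0.84 (SE 0.46), or 0.80 and 0.28 without animal 826, and 12 of the 21 listed members were under 1 FPKM in every library. The goblet cell median was 0.62 without animal 139 (adjusted p = 0.206), 0.74 without 140 (adjusted p = 0.122) and 0.27 without 826 (adjusted p = 0.00799), and without the filter on low values it was 0.16 (adjusted p = 0.0303).

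**Figure D3:**
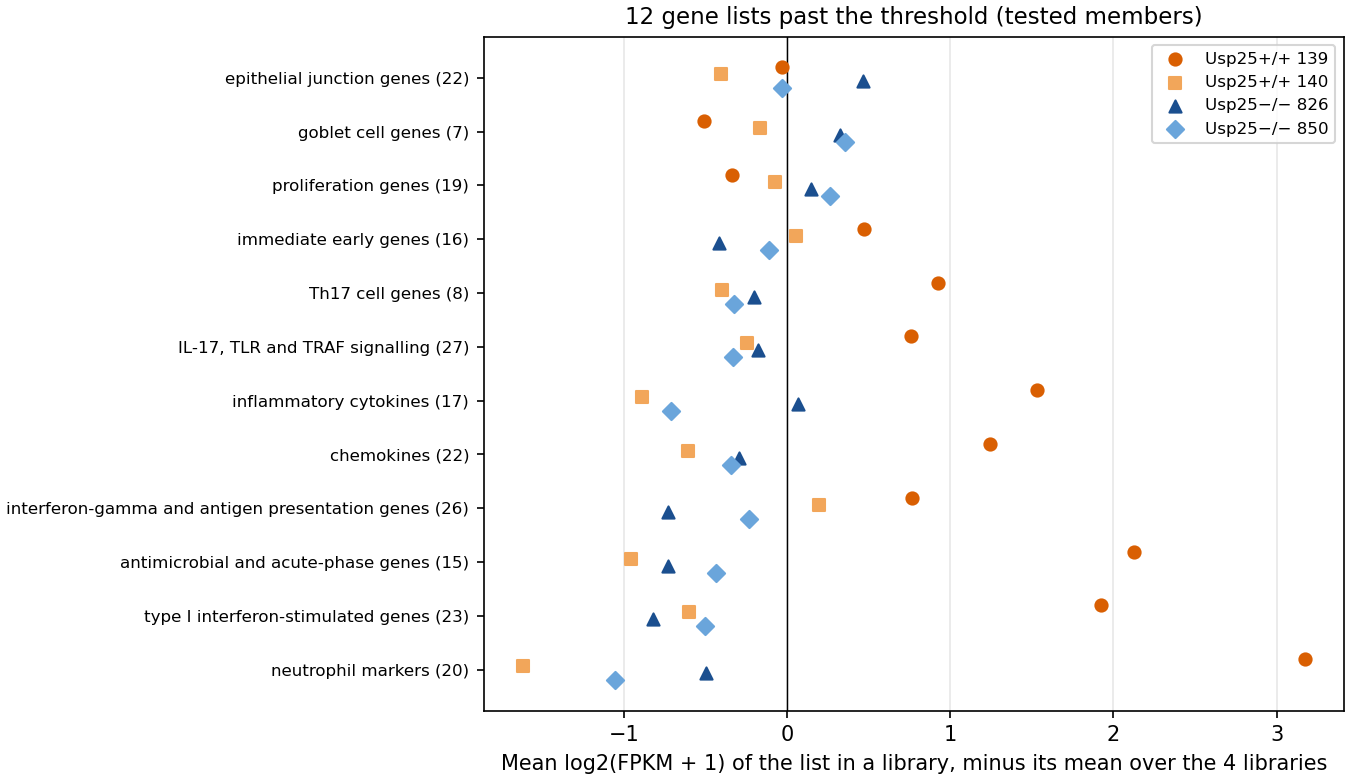
Mean log2(FPKM + 1) of each of the 12 lists that passed the preset test, minus its mean over the 4 libraries, with 1 point per library and the number of tested members in parentheses. The mean of the neutrophil markers was 9.25 in Usp25+/+ 139 and 4.46, 5.58 and 5.02 in 140, 826 and 850.

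The other 15 lists did not pass camera with the preset correlation. Their median log2 fold changes were -0.34 for endothelial markers (adjusted p = 0.0830), 0.23 for fatty acid oxidation (0.0830), -0.29 for T and NK cells (0.122), -0.09 for monocytes and macrophages (0.152), 0.14 for the unfolded protein response (0.184), 0.35 for adipocyte markers (0.229) and 0.20 for absorptive colonocytes (0.229). They were -0.34 for B and plasma cells (0.292), 0.10 for smooth muscle (0.295), -0.28 for STAT3 targets (0.502), 0.15 for fibroblasts and matrix (0.567), -0.08 for matrix proteases (0.827) and -0.42 for squamous epithelium (0.861). Wnt target and crypt stem cell genes had a median of -0.16 while camera placed them higher (0.502). Of these 15 medians, 13 changed sign when some library was left out and 6 under another filter, pseudocount or scaling, while those of adipocyte markers and of the unfolded protein response kept their sign. When a library was left out, 10 of the 15 passed at least once. Without animal 139 these were endothelial markers at -0.84 (adjusted p = 1.49e-04), monocytes and macrophages at -0.27 (0.0312), the unfolded protein response at 0.27 (0.0257) and matrix proteases at 0.43 (0.0120). Without 140 they were fatty acid oxidation at 0.51 (5.60e-04), matrix proteases at -0.47 (0.0265) and squamous epithelium at -1.43 (0.0101), and without 826 fibroblasts and matrix at 0.47 (3.28e-05) and B and plasma cells at 0.14 (0.0307). Without 850 they were T and NK cells at -0.62 (4.67e-05), endothelial markers at -0.71 (3.59e-04), absorptive colonocytes at 0.45 (0.00394) and B and plasma cells at -0.73 (0.0148). Among the members, Pparg had a log2 fold change of 0.90 (SE 0.42; 0.42 without 139), Socs3 of -0.90 (SE 0.34), Guca2a of 2.55 (SE 0.66; 1.63 without 826) and Mmp13 of 1.66 (SE 0.60; 0.97 without 140). Lists with fewer than 5 tested members were not tested as sets. Their median log2 fold change was 1.10 for 4 mast cell and eosinophil genes. These went both ways, with Kit (-0.30) and Siglecf (-0.63) against the higher Mcpt1 and Mcpt2. The median was 1.19 for 2 enteroendocrine genes, 1.25 for 3 erythroid genes, 0.38 for 3 enteric neuron genes and 0.47 for 1 skeletal muscle gene. Mean log2(FPKM + 1) in 139, 140, 826 and 850 was 3.10, 1.26, 4.89 and 1.84 for the enteroendocrine genes. For the erythroid genes it was 1.17, 2.49, 3.75 and 2.53, and for the enteric neuron genes 1.68, 2.59, 2.21 and 2.26. For the skeletal muscle gene it was 2.62, 4.08, 3.88 and 3.76. Except in the erythroid genes, these means overlapped between the genotypes.

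Libraries did not pair by genotype in their similarity. Across 12011 genes, which are not independent replicates, Pearson's r of log2 values was 0.967 between Usp25+/+ 140 and Usp25-/- 850, against 0.955 between the Usp25-/- libraries and 0.868 between the Usp25+/+ libraries. Animal 139 stood apart from each of the others, with r of 0.868 to 0.882. It also had 2698 genes above 0 in no other library, against 176, 522 and 203 in 140, 826 and 850. The shares of the non-coding RNAs Rn45s and Mir6236 separated the genotypes without overlap, which chance gives in 33.3% of cases. The ribosomal RNA precursor Rn45s took 0.528% and 1.22% of the FPKM total in 139 and 140 and 1.30% and 2.03% in 826 and 850. Mir6236 took 0.273% and 0.549% against 0.889% and 1.46%. All Mir and Snor genes together took 0.543% and 0.740% against 1.11% and 1.67%. This total includes Mir6236, which made up most of it in 140, 826 and 850, and the remainder did not separate the genotypes. The protein-coding Lars2 took 0.469% and 3.11% against 2.45% and 4.84%, with overlap.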

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

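No test in this part was chosen after the result was seen. The count of 0 genes past the limma threshold was the same under all 11 other adjusted settings and in each fit without a library, and 375 genes had an unadjusted p under 0.05, or 103 to 2577 when a library was left out. Usp25 stayed lower in Usp25-/- in every setting, with log2 fold changes of -3.65 to -2.49 when a library was left out. The 71 genes at least 1 log2 unit apart became 141 with a pseudocount of 0.1, 19 with a pseudocount of 5, 42 with a mean of at least 5 FPKM, 120 with libraries rescaled to one common total, 415 at a gap of 0.5 and 10 at a gap of 2. Leaving out a library gave 172 to 1382, since fewer libraries need to stay apart, and without Usp25+/+ 140 more were lower (845) than higher (537). The 12 lists past camera became 0 with an estimated correlation and 0 with fry, and 10 to 13 when a library was left out. Without Usp25+/+ 139 the median turned to 0.61 for inflammatory cytokines (range over left-out libraries -2.15 to 0.61), 0.0096 for chemokines (-1.66 to 0.0096), 0.0999 for antimicrobial genes (-2.63 to 0.0999), 0.811 for neutrophil markers (-3.91 to 0.811) and 0.429 for matrix proteases (-0.466 to 0.429), which also turned without Usp25-/- 850 (0.282) and with a mean of at least 5 FPKM (0.0698). The median of B and plasma cells turned to 0.143 without Usp25-/- 826, 0.386 without Usp25+/+ 140, 0.0374 without the filter and 0.0245 with rescaled libraries (-0.734 to 0.386 over left-out libraries). Of the 12 lists, 7 passed in all 8 other filters, pseudocounts and scalings. The goblet cell genes passed in the 7 in which they could be tested, since a mean of at least 5 FPKM left fewer than 5 members, but without the filter their median fell from 0.547 to 0.159. Without the filter on low values the share of higher genes at an unadjusted p of 0.05 was 55.7%, against 67.7% with it. The cause of these shifts was not tested, and the unknown depth leaves counting error unmeasured.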

Other observations

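The tests of tissue, of animal 139, of epithelial share and of stomach genes were chosen after the results were seen, and only the count over other splits was planned.

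The antigen presentation list held genes that moved in opposite ways between the Usp25+/+ libraries. The class II genes H2-Aa and H2-Ab1 were listed at 238 and 221 FPKM in animal 139 and at 1113 and 880 FPKM in animal 140, with 576 and 387 in 826 and 623 and 472 in 850. Their invariant chain Cd74 was listed at 540, 2540, 1096 and 1742 FPKM in 139, 140, 826 and 850. Gbp2 was highest in 139, at 554 FPKM against 24.8, 12.7 and 18.7. Alveolar macrophage genes, 14 chosen after the data were seen, had library medians of 102, 200, 153 and 151 FPKM, and the macrophage lysozyme Lyz2 was listed at 12613, 38922, 31444 and 32571 FPKM. In 8 genes both Usp25-/- libraries were listed at 0 with both Usp25+/+ libraries at 1 FPKM or more, and 8 genes showed the converse. Under the other splits these counts were 20 and 8, and 10 and 4.

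All 4 libraries held lung genes, little of the colon genes, and Y-linked genes with Xist near 0, although the labels say colon of females. Colon RNA mixed with lung RNA is argued against by the colonocyte and goblet cell genes, whose highest library median was 0.297 FPKM. Colon that had lost its epithelium would keep its muscle, and 5 visceral smooth muscle genes had a highest library median of 0.530 FPKM. What stays open is that the files may hold RNA of lung from male animals under the labels of another set of samples, since the lowest library median of the 16 lung genes was 54.0 FPKM. This hypothesis was formed and tested on the same values, while Usp25 followed the genotype labels.

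Animal 139 had the highest level of all 20 tested neutrophil markers, with 3 genes shared with the antimicrobial list, and of all 23 type I interferon-stimulated genes. Easier detection of low genes is argued against for the neutrophil markers: the 15 with a mean of at least 10 FPKM in the other 3 libraries had a median log2 ratio of 4.22 to that mean in animal 139 (quartiles 3.57 and 4.78). Genotype alone would also place animal 140 above both Usp25-/- libraries, which held for 0 of 20 neutrophil markers. Chance gives 33.3% for a single gene, but these markers moved together, with an estimated correlation of 0.98. They thus amount to little more than a single observation on animal 140, which cannot decide on genotype. Among the interferon genes, animal 140 lay above both Usp25-/- libraries in 10 of 23. Detection stays open for them too, as only 6 reached 10 FPKM in the other libraries, with a median ratio of 2.14 (quartiles 0.98 and 2.48). More neutrophils could also bring these 23 transcripts, which had a median log2 ratio of 2.51, and as no value separates interferon genes of neutrophils from those of other cells, these explanations cannot be told apart.

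Tff1, Gkn1, Gkn2 and the rest of the 12 widest-gap genes above in Usp25-/- may reflect tissue makeup. Stomach tissue that expresses the 6 chosen stomach gland and pit genes is argued against by their higher Usp25-/- library median of 0 FPKM. Of these 6 genes, 5 were under 1 FPKM in every library. Their median cannot exclude an epithelium that makes the 12 widest-gap genes without them. A larger share of epithelial cells stays open. The 12 genes exceeded 8 general epithelial genes, 5 of them also in the junction list, by at least 1.55 log2 units in median ratio. The epithelial genes themselves had a median log2 ratio to the Usp25+/+ mean of 2.05 in 826 and 0.53 in 850. The 12 widest-gap genes higher in 140 and 850 than in 139 and 826 exceeded them by 2.63. Those were picked from all tested genes, without the minimum of 5 FPKM and without passing over predicted genes. Animal 826, with the highest epithelial median, also lay on the lower side there. This comparison therefore cannot show how much of the difference comes from picking by gap. As for chance, 2 of the 3 splits gave at least as many genes 1 log2 unit apart, 71 in the real one and 113 as the highest other, and 3 splits are too few for a share under 0.05. Genotype stays open as an untested explanation.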
